A study of Mus musculus with 22 samples.

How the data were processed

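RNA of the hypothalamus of 22 lean male mice was, per the labels, extracted with Trizol, cleaned on columns, labelled with biotin by a whole-transcript kit and measured on Affymetrix arrays. The deposited log2 values were made by the authors with RMA, which corrects background, quantile-normalizes arrays and summarizes probes into probe sets; the RMA version and the probe set annotation behind it are not given in the sources used here. The table held 23492 probe sets for 22 arrays, with values from 3.83 to 15.2, and 0 columns of other series. The range and the array medians were checked and fit log2 intensities. The values were all but identical in 0 pairs of arrays, so no array was counted as a copy of another.

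Gene symbols came from the platform's annotation. Exactly 1 symbol was given for 20228 probe sets, several for 1399 and none for 1865. The 20228 name 18704 genes, and for the 809 genes with more than 1 probe set, the probe set with the highest mean over all arrays was kept. Genes were tested if above their array's median in at least 3 arrays, which left 9880 genes and set aside 8824 as dim. Arrays of both treatments count in this filter, so a gene can enter through a rise in celastrol arrays alone. Chance alone gives about 494 of 9880 genes at an unadjusted p under 0.05. Arrays have no read depth, and their number per group limits the precision.

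Groups were read from the labels: DMSO or celastrol at 6 h, 1 day and 4 days. One linear model with 6 group means was fitted to all 22 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 16 residual and 6.06 prior degrees of freedom; median residual SD 0.0758 on the log2 scale), and genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes. Contrasts were celastrol against DMSO at each time, their equally weighted average, the 3 differences between times, and DMSO between times. The tests were two-sided. Exact permutation tests, also two-sided, exchanged labels within a time; the smallest p they can give is 0.0286 for 4 against 4 and for 3 against 4 arrays. Intervals are at 95%. The choices of test, filter, gene lists, named genes and alternatives were made before the data were examined.

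A total of 26 gene lists were written from general knowledge: 13 of responses and pathways (feeding neuropeptides and receptors, leptin and JAK-STAT3, unfolded protein response, heat shock, NRF2, acute phase with interleukin-1 and NF-kB, interferon, glucocorticoid, fasting and fatty acid oxidation, cholesterol biosynthesis, circadian clock, immediate early genes, oxidative phosphorylation) and 13 of cell types, neighbouring tissue and RNA quality. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, Benjamini-Hochberg over the lists; beside it stand camera with an estimated correlation and fry, a self-contained test of whether a list's genes move on balance in 1 direction. Some genes stand on more than 1 list.

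The named genes followed a rule. At each time they were up to 10 higher and 10 lower genes with the largest change among those passing with every celastrol array on the same side of the DMSO mean, or, where none passed, the 5 higher and 5 lower with the smallest p. For the average and the differences the rule took 5 each way, and for DMSO alone 3. For each list it took up to 4 members that passed, or up to 2 with the smallest p. Always named were Lcn2, Lepr, Socs3, Pomc, Npy, Hspa5 and a pair not analysed here, Il1r1 and Agrp. Predicted genes and non-coding RNAs were counted but not named. Genes given in a comparison where the rule did not name them, members named from the counts adjusted over a list alone, and Wfdc17, Slfn5 and Srarp were chosen after their values were seen.

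The alternatives were no filter on level, a stricter filter (11 arrays), the mean of a gene's probe sets, quantile normalization again, median centring, limma-trend, robust eBayes, array weights, only the groups compared, the replicate number as a block, all probe sets, the leading principal component of the residuals as a covariate, and leaving out each array in turn. A further one, without the 2 arrays with the lowest mean correlation with their group (DMSO 1 day replicate 1 and celastrol 1 day replicate 2), was chosen after seeing the data, as was testing the lists with no filter on level and an estimated correlation together, and the acute-phase list without Lcn2. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

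The steps were tested on simulated data with the same groups and spread, in which 200 of 9880 genes were changed, 5 times per setting. Genes were drawn independently of each other, so the rates below do not cover genes that vary together. True log2 changes of 0.25, 0.5 and 1 were recovered in 73.3%, 97.8% and 99.7% of genes at 6 h, in 64.9%, 97.7% and 99.7% at 1 day, in 64.5%, 97.2% and 99.7% at 4 days, and in 97.5%, 99.9% and 99.9% on the average. For the differences between times recovery was 27.2%, 90.8% and 99.6% (1 day minus 6 h), 28%, 91% and 99.3% (4 days minus 6 h), and 17.8%, 89% and 99.2% (4 days minus 1 day). For DMSO it was 74.8%, 98.8% and 99.7%, then 70.9%, 98.6% and 100%, then 69.9%, 98.4% and 99.8%, in the same order of times. A simulated shift of 0.2 in the microglia list at 4 days was called in 20 of 20 runs, with 2 calls of other lists. Those runs also drew genes independently, so they do not show how the list test behaves when the genes of a list vary together.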

Results

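Messenger RNA of the hypothalamus was measured on 22 arrays from lean male C57BL/6J mice, 8 weeks old and fed normal chow for 2 weeks. The mice received intraperitoneal celastrol, a triterpenoid of the thunder god vine, or its vehicle dimethyl sulfoxide (DMSO), for 6 h, 1 day or 4 days. There were 4 DMSO arrays at each time, 4 celastrol arrays at 6 h, 3 at 1 day and 3 at 4 days. The labels call them biological replicates. The labels give a celastrol dose of 250 µg per kg beside the 6 h treatment and a volume of 100 µl beside the treatments of 1 and 4 days, so the dose of the later groups is not given in the sources used here. Median log2 intensities per array lay between 8.58 and 8.66, and the mean correlation of an array with the others of its group lay between 0.989 and 0.995. Tests covered 9880 genes above a minimum level, and the small number of arrays per group limited the precision.

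The 3 time-matched comparisons were averaged with equal weight, so a large change at 1 time can carry the average. Celastrol raised 6 genes and lowered 0 at an adjusted p under 0.05 (limma). Osmr (probe set 10427471), which encodes the receptor subunit for oncostatin M, rose 1.71-fold (log2 change 0.77, SE 0.10, 95% interval 0.56 to 0.98, adjusted p = 5.26e-04), and all 10 celastrol arrays lay above the DMSO mean of their time. Ptgs2 (probe set 10350516), the inducible cyclooxygenase of prostaglandin synthesis, rose 1.70-fold (log2 change 0.76, SE 0.09, 95% interval 0.57 to 0.96, adjusted p = 4.92e-04), with 9 of 10 arrays above. Acer2 (probe set 10505779), an alkaline ceramidase, rose 1.30-fold (log2 change 0.38, SE 0.06, adjusted p = 0.00953, 9 of 10 arrays), and Ier3 (probe set 10444890), an immediate early target of NF-kB, rose 1.18-fold (log2 change 0.24, SE 0.04, adjusted p = 0.00598, 9 of 10 arrays). Adamts9 (probe set 10546430), a secreted metalloprotease, rose by a log2 change of 0.16 (SE 0.03, adjusted p = 0.0278, 9 of 10 arrays), and Sbno2 (probe set 10370721), a transcriptional co-regulator downstream of STAT3, by 0.14 (SE 0.02, adjusted p = 0.0168, 10 of 10 arrays). An exact permutation of labels within each time gave p = 3.5e-05 for Osmr and for Ptgs2, 2.22e-04 for Acer2 and 5.83e-05 for Ier3. These p-values are unadjusted and belong to genes called from the same arrays, so they are not separate evidence.

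**Figure D1:**
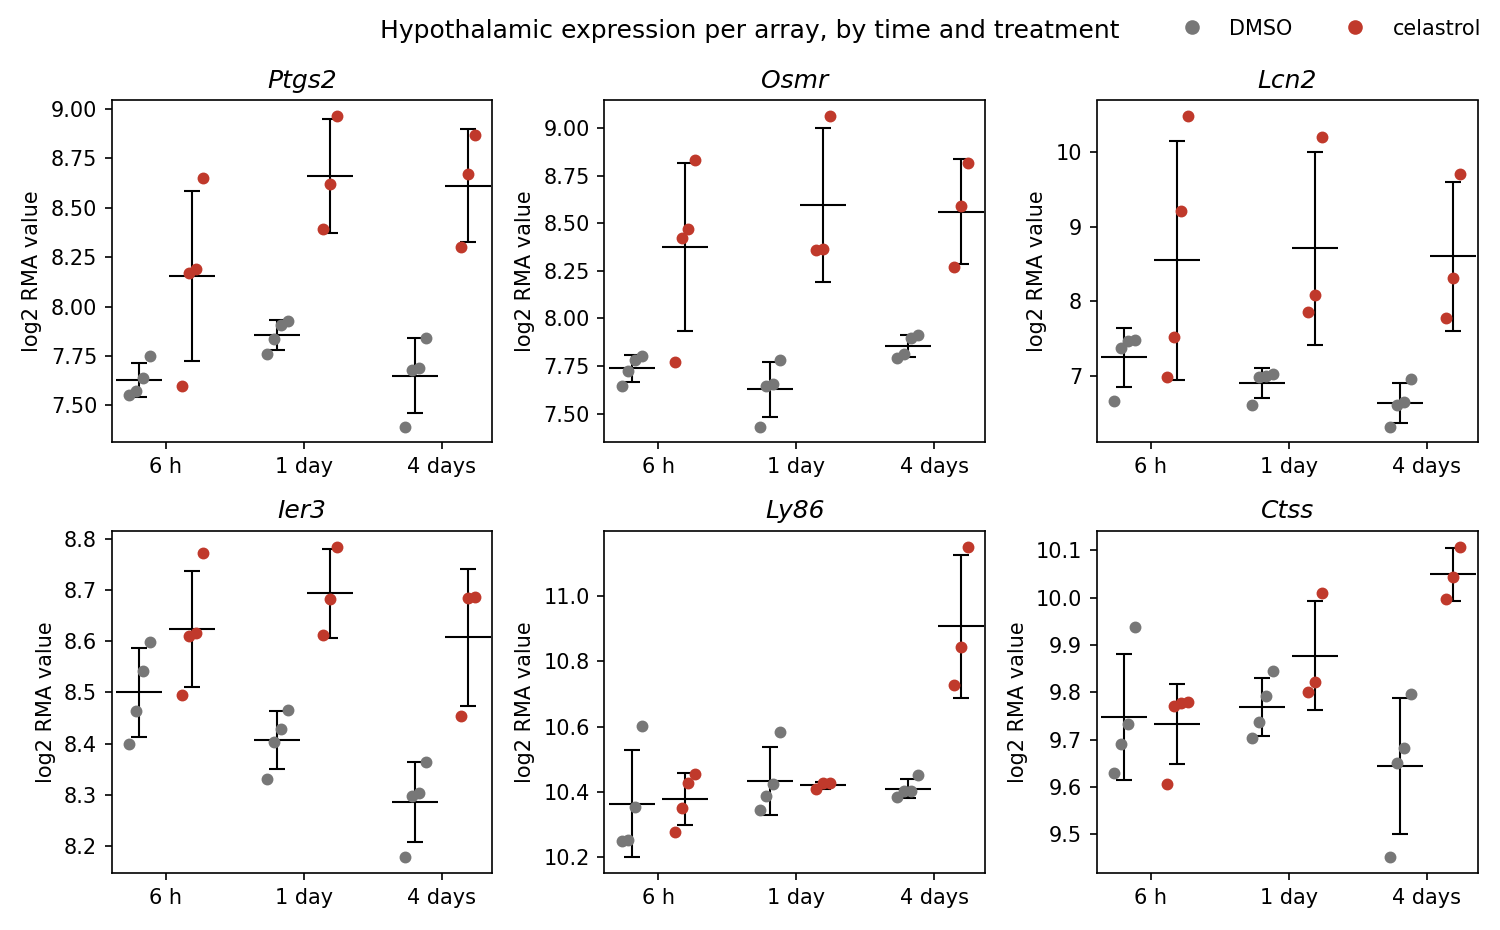
Log2 intensity (vertical axis) of Ptgs2, Osmr, Lcn2, Ier3, Ly86 and Ctss in each array, by treatment and time (horizontal axis); points are arrays, and bars are group means ± SD. Ptgs2 at 4 days averaged 8.61 after celastrol (n = 3) and 7.65 after DMSO (n = 4).

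Lcn2 (probe set 10481627), the siderophore-binding acute-phase protein lipocalin 2, had an average log2 change of 1.68 (SE 0.34, 95% interval 0.98 to 2.39), and 9 of 10 arrays lay above DMSO. Its DMSO group means, from 6.64 to 7.25, lay near or below the lower quartile of the arrays and were not shown to be above background, so the size of the change is uncertain. It did not pass over all genes (adjusted p = 0.0813, range over the alternatives, arrays left out included, 0.0132 to 0.318), while its own exact permutation p was 8.16e-05. It passed with limma-trend (adjusted p = 0.0462), with the residual component (0.0220), and without celastrol 6 h replicate 1 (log2 change 1.86), celastrol 6 h replicate 4 (1.80) or celastrol 4 days replicate 3 (1.82). Osmr, Ptgs2, Acer2 and Ier3 passed in all 33 alternative settings that tested them. Adamts9 passed in 15 of 33. It was lost with no filter (adjusted p = 0.0753), the stricter filter (0.0713), median centring (0.0577), limma-trend (0.0775) and, in a setting chosen after the data were seen, without the 2 least typical arrays (0.0617). It was also lost, at log2 changes from 0.15 to 0.16, without DMSO 6 h replicate 2 or 3, DMSO 1 day replicate 2 or 3, DMSO 4 days replicate 2, 3 or 4, celastrol 6 h replicate 3 or 4, celastrol 1 day replicate 1 or 3, and celastrol 4 days replicate 1 or 2. Sbno2 passed in 28 of 33. It was lost with the replicate block (adjusted p = 0.437), limma-trend (0.204) and no filter (0.0530), and without celastrol 1 day replicate 1 (0.13) or celastrol 4 days replicate 1 (0.13).

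Among the lists of genes fixed in advance, 7 of 26 were called on the average by camera with a preset correlation, 6 higher and 1 lower, and 4 held with an estimated correlation and by fry, which tests each list on its own and not against other genes. The acute-phase, interleukin-1 and NF-kB list rose: all 10 tested members of 40 listed were higher (mean log2 change 0.32, 95% interval 0.20 to 0.43; adjusted p = 2.43e-13, and 0.00214 with an estimated correlation). Of them 1 passed over all genes and 6 adjusted over the list alone, namely Lcn2, Ptgs2, Nfkbia, Vcam1, Serpina3n and C4b. Lcn2 and Ptgs2 were above the array median in 0 DMSO arrays and entered the tested set through celastrol arrays, so the tested members were partly selected by their change. With no filter on level, 32 of 37 members were higher and the mean was 0.14 (adjusted p = 2.13e-12, and 0.0137 with an estimated correlation, a setting chosen after the data were seen). Without Lcn2, also chosen after, the mean of the other 9 tested members was 0.16 (adjusted p = 1.58e-10, and 0.00473 with an estimated correlation). The leptin and JAK-STAT3 list rose, with 13 of 15 tested members higher (mean 0.11, 95% interval 0.06 to 0.16; adjusted p = 7.07e-08, and 0.0225 with an estimated correlation). Its count was 1 over all genes and 5 adjusted over the list alone: Osmr, which also entered through celastrol arrays alone, Pim3, Serpina3n, Fosl2 and Il6ra. The glucocorticoid response list rose, with 23 of 24 members higher (mean 0.12, 95% interval 0.04 to 0.19; adjusted p = 2.09e-16, and 0.0248 with an estimated correlation). None of its members passed over all genes and 13 did adjusted over the list alone, among them Fkbp5, Sgk1, Tsc22d3 and Pdk4. Microglia and macrophage markers rose, with 12 of 13 higher (mean 0.09, 95% interval 0.05 to 0.13; adjusted p = 2.72e-09, and 0.00624 with an estimated correlation), 0 over all genes and 6 adjusted over the list alone. The means behind this average were 0.04, -0.00 and 0.23 at 6 h, 1 day and 4 days.

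The other calls on the average were lost with an estimated correlation. Fasting and fatty acid oxidation genes averaged 0.05 higher (adjusted p = 0.00783, and adjusted p = 0.448 with an estimated correlation), and this call was also lost without celastrol 6 h replicate 3, at a mean of 0.04. Pdk4, which restrains pyruvate oxidation, had a log2 change of 0.21 in the same direction in 10 of 10 arrays (adjusted p = 0.167), and Plin4, a lipid droplet coat protein, 0.32 (adjusted p = 0.679, 9 of 10). Cholesterol biosynthesis genes averaged -0.02, with 6 of 21 above 0 (adjusted p = 0.00509, and adjusted p = 0.448 with an estimated correlation). Astrocyte markers averaged 0.03 higher, with 19 of 20 above 0 (adjusted p = 0.0274, and adjusted p = 0.641 with an estimated correlation). The astrocyte call was also lost without DMSO 6 h replicate 2 (mean 0.02), DMSO 1 day replicate 2 (0.02), DMSO 4 days replicate 2 (0.02), celastrol 6 h replicate 3 (0.02) or celastrol 1 day replicate 2 (0.03), and without the 2 least typical arrays (adjusted p = 0.108). Without celastrol 4 days replicate 2, 12 lists were called on the average.

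After 6 h of celastrol, Osmr, Ptgs2 and Lcn2 lay higher on average, but 0 genes passed by limma over all genes (lowest adjusted p = 0.895), and 505 had an unadjusted p under 0.05, where chance alone gives about 494. Of the 505, 419 were higher and 86 lower, and the median log2 change over all tested genes was 0.02. The values were thus shifted to 1 side, and the cause was not tested. Osmr was 1.55-fold higher (log2 change 0.64, SE 0.16, n = 4 each), with all 4 celastrol arrays above the DMSO mean. Ptgs2 was 1.44-fold higher (0.52, SE 0.16), with 3 of 4 above. Celastrol 6 h replicate 1 lay within the DMSO range for Osmr (7.77, DMSO 7.64 to 7.80), Ptgs2 (7.60, DMSO 7.55 to 7.75) and Lcn2 (6.98, DMSO 6.67 to 7.49). Lcn2 averaged 1.29 higher on the log2 scale (SE 0.56) with a wide spread, from 6.98 to 10.5 among the celastrol arrays, and 3 of 4 above the DMSO mean. None of the 3 passed over all genes (adjusted p = 0.895 for each). The 10 genes named by the rule for their p-values did not pass either (adjusted p = 0.895). The 5 with higher values were Idh1, the cytosolic isocitrate dehydrogenase (log2 change 0.32, SE 0.08), Vps26c (0.25), Glra3 (0.20), Uprt (0.19) and Hepacam, a glial adhesion protein (0.15). The 5 with lower values were Acr (-0.26), Zfp28 (-0.17), Leng8 (-0.16), Chpf2 (-0.16) and Ppm1m (-0.14). In all 10, the 4 celastrol arrays lay on the same side of the DMSO mean.

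At 6 h, 5 of 26 lists were called with the preset correlation, 3 higher and 2 lower, and 0 with an estimated correlation or by fry. The leptin and JAK-STAT3 list had 13 of 15 members higher (mean log2 change 0.12; adjusted p = 0.0231, and adjusted p = 0.601 with an estimated correlation), and the acute-phase list 8 of 10 (mean 0.23; adjusted p = 0.0231, and adjusted p = 0.601 with an estimated correlation). Each had 0 members past the threshold over all genes and 1 adjusted over the list alone, Osmr and Ptgs2. Serpina3n, a protease inhibitor on both lists, was 0.17 higher in 4 of 4 arrays (adjusted p = 0.895). Astrocyte markers had 19 of 20 members higher (mean 0.06; adjusted p = 0.0231, and adjusted p = 0.804 with an estimated correlation), such as the membrane protein Mlc1 at 0.12. Pituitary markers, which a hypothalamic dissection can carry, had 1 of 6 higher (mean -0.51; adjusted p = 0.0018, and adjusted p = 0.601 with an estimated correlation). Growth hormone, Gh, differed by -1.95 (SE 0.74, adjusted p = 0.895), with a mean of 9.67 and an SD of 1.71 in DMSO, 7.71 and 0.126 in celastrol, and an exact permutation p of 0.114. Gh and Chga (-0.15) passed adjusted over the list alone. Regional markers of hypothalamic neurons had 6 of 23 higher (mean -0.05; adjusted p = 0.00122, and adjusted p = 0.601 with an estimated correlation).

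Each of these calls was lost without 1 or more of the arrays. Without DMSO 6 h replicate 4, 0 lists were called, with means of 0.10 for the leptin list, 0.22 for the acute-phase list, 0.05 for astrocytes, -0.23 for pituitary markers and -0.04 for hypothalamic markers. Without celastrol 6 h replicate 3, 2 lists remained, and the leptin (0.08), acute-phase (0.17) and astrocyte (0.03) calls were lost. The leptin and acute-phase calls were lost without DMSO 6 h replicate 3 (0.13 and 0.25), the acute-phase call without celastrol 6 h replicate 2 (0.17), the astrocyte call without DMSO 6 h replicate 2 (0.05), and the hypothalamic call without celastrol 6 h replicate 4 (-0.01). Without celastrol 6 h replicate 1, 9 lists were called. With no filter on level the acute-phase call at 6 h was lost, at a mean of 0.08 over 37 members, 25 of them higher (adjusted p = 0.0531). It was also lost without Lcn2 (0.11, adjusted p = 0.0843) and without the 2 least typical arrays (adjusted p = 0.0538).

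After 1 day of celastrol, Osmr was 1.96-fold higher (log2 change 0.97, SE 0.18, 95% interval 0.60 to 1.34; n = 3 celastrol and 4 DMSO), Ptgs2 1.74-fold (0.80, SE 0.17), Adamts9 1.22-fold (0.29, SE 0.05) and Sbno2 1.17-fold (0.22, SE 0.04). All 3 celastrol arrays lay above all 4 DMSO arrays for each of them. None passed over all genes: the adjusted p was 0.0852 for Osmr and Adamts9, 0.0867 for Sbno2 and 0.186 for Ptgs2, and an exact permutation gave each 0.0286, the smallest p this design allows. The rule also named Syt6, a synaptotagmin (0.19, adjusted p = 0.222). The genes with lower values were Pank3, a pantothenate kinase (-0.21), Ddx47 (-0.19), Vma21 (-0.19), Mgat2 (-0.18) and Caml (-0.18), each lower in 3 of 3 arrays, with adjusted p between 0.356 and 0.478. Lcn2 averaged 1.80 higher (SE 0.60, adjusted p = 0.698, 3 of 3 arrays), and Nfkbia, the inhibitor that NF-kB itself induces, 0.36 (SE 0.09, adjusted p = 0.446, 3 of 3).

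In total 0 genes passed at 1 day by limma and 658 had an unadjusted p under 0.05, 161 higher and 497 lower. Other settings called 1 to 5 genes: 5 with array weights, 5 with the leading component of the residuals as a covariate, and 1 with no filter on level. Leaving out 1 array gave 1 gene without DMSO 1 day replicate 4, 2 without celastrol 6 h replicate 1 and 4 without celastrol 6 h replicate 3.

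At 1 day, 5 lists were called with the preset correlation, 4 higher and 1 lower, and 0 with an estimated correlation or by fry. Glucocorticoid response genes had 21 of 24 members higher (mean log2 change 0.15; adjusted p = 3.99e-10, and adjusted p = 0.227 with an estimated correlation), 0 over all genes and 2 adjusted over the list alone, Nfkbia and the kinase gene Pim3 (0.18, adjusted p = 0.659 over all genes, 3 of 3 arrays). The acute-phase list averaged 0.31 higher (95% interval 0.10 to 0.52; adjusted p = 3.78e-04, and adjusted p = 0.227 with an estimated correlation), 0 over all genes and 3 adjusted over the list alone, Lcn2, Nfkbia and Ptgs2. With no filter its mean was 0.18, with 29 of 37 members higher (adjusted p = 4.19e-07, and adjusted p = 0.166 with an estimated correlation). Without Lcn2 its mean was 0.14 (adjusted p = 0.00516, and adjusted p = 0.341 with an estimated correlation). The leptin and JAK-STAT3 list had 10 members higher (mean 0.09; adjusted p = 0.00812, and adjusted p = 0.400 with an estimated correlation), 0 over all genes and 3 adjusted over the list alone, Osmr, Pim3 and Il6ra. This call was lost without DMSO 1 day replicate 2 (0.07) or celastrol 1 day replicate 1 (0.03) and with the replicate block (adjusted p = 0.0559). Oxidative phosphorylation genes were lower in 36 of 37 members (mean -0.07, 95% interval -0.12 to -0.02; adjusted p = 9.72e-05, and adjusted p = 0.400 with an estimated correlation), 0 of them past the threshold over all genes or adjusted over the list alone. Examples are the respiratory chain genes Ndufa4 (-0.13, adjusted p = 0.698) and Ndufs3 (-0.10, adjusted p = 0.720), each lower in 3 of 3 arrays. That call was lost without DMSO 1 day replicate 1 (-0.04) and without the 2 least typical arrays (-0.03, adjusted p = 0.0814). Astrocyte markers averaged 0.03 higher (adjusted p = 0.0397, and adjusted p = 0.913 with an estimated correlation), a call lost without DMSO 1 day replicate 2 (0.02) or 4 (0.03) and without celastrol 1 day replicate 2 (0.03) or 3 (0.02). It was also lost with no filter (adjusted p = 0.251), quantile normalization again (mean 0.04), the replicate block (adjusted p = 0.0689) and without the 2 least typical arrays (0.120). Without DMSO 1 day replicate 2, 3 lists were called.

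After 4 days of celastrol, 5 genes passed by limma, 3 higher and 2 lower (n = 3 celastrol and 4 DMSO), and all 3 celastrol arrays lay on the same side of the DMSO mean for each. Ptgs2 rose 1.95-fold (log2 change 0.96, SE 0.17, 95% interval 0.61 to 1.31, adjusted p = 0.0443). The others that rose are microglial: Ly86 (probe set 10404606), the MD-1 partner of a Toll-like receptor homologue on myeloid cells, rose 1.41-fold (0.50, SE 0.08, 95% interval 0.32 to 0.67, adjusted p = 0.0443), and Ctss (probe set 10494271), the lysosomal protease cathepsin S, 1.32-fold (0.40, SE 0.07, 95% interval 0.25 to 0.56, adjusted p = 0.0493). Ndnf (probe set 10538802), a secreted neurotrophic factor, fell by 0.40 on the log2 scale (SE 0.07, adjusted p = 0.0493), and Id2 (probe set 10399691), a helix-loop-helix inhibitor of differentiation, fell by 0.27 (SE 0.05, adjusted p = 0.0493). Exact permutation gave p = 0.0571 for Ndnf and 0.0286, the smallest p here, for the other 4. Lcn2 averaged 1.96 higher on the log2 scale (SE 0.60) in 3 of 3 arrays but did not pass (adjusted p = 0.741, range over the alternatives 0.0959 to 1.0). Further values that did not pass were Osmr 0.71 (SE 0.18, adjusted p = 0.258), the stress-induced mTOR inhibitor gene Ddit4 0.45 (adjusted p = 0.0601), the endothelial genes Vwf 0.46 (adjusted p = 0.0709) and Tek 0.24 (adjusted p = 0.123), Nfkbia 0.40 (adjusted p = 0.133), Fosl2 0.26 (adjusted p = 0.149) and the small heat shock protein gene Cryab -0.25 (adjusted p = 0.248), all in 3 of 3 arrays. Over the alternatives their adjusted p ranged from 0.0457 to 0.999 for Osmr, 0.0203 to 0.335 for Ddit4, 0.0258 to 0.706 for Vwf and 0.0453 to 0.798 for Tek. They ranged from 0.0666 to 0.742 for Nfkbia, 0.0196 to 0.734 for Fosl2 and 0.115 to 0.999 for Cryab. Ddit4 passed in 7 of 35 settings, Vwf in 4 of 34, and Osmr, Tek and Fosl2 in 2 each.

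An unadjusted p under 0.05 was found for 362 genes at 4 days (252 higher and 110 lower), fewer than the 494 of chance, and the 5 calls lay close to the threshold. Their adjusted p ranged over the alternatives from 0.00208 to 0.262 for Ly86, from 0.00208 to 0.280 for Ptgs2, from 0.0196 to 0.348 for Ctss, from 0.00587 to 0.348 for Ndnf and from 0.0125 to 0.262 for Id2. Quantile normalization a second time gave 3 calls, 1 higher and 2 lower. Of the other settings, array weights called 16 genes, the residual component 13, limma-trend 8, robust variances 1, no filter on level 3, all probe sets 0, and the replicate block 0 (adjusted p from 0.202 to 0.323 for the 5 genes). Only the groups compared called 7, of which Ptgs2 alone is among the 5, and the setting without the 2 least typical arrays, chosen after the data were seen, called 3. Leaving out 1 array gave 9 without DMSO 6 h replicate 2 and 8 without DMSO 1 day replicate 2. It gave 3 without DMSO 6 h replicate 3, celastrol 6 h replicate 1 or celastrol 4 days replicate 3, and 2 without celastrol 6 h replicate 3. It gave 1 without DMSO 1 day replicate 1 or DMSO 4 days replicate 2. It gave 0 without DMSO 1 day replicate 3 or 4, DMSO 4 days replicate 1, 3 or 4, celastrol 6 h replicate 2 or 4, celastrol 1 day replicate 3, or celastrol 4 days replicate 1 or 2.

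Microglia and macrophage markers rose together at 4 days: all 13 tested members of 22 listed were higher (mean log2 change 0.23, 95% interval 0.16 to 0.30). The call held with the preset correlation (adjusted p = 7.12e-20), with an estimated correlation (adjusted p = 1.64e-04), by fry (adjusted p = 9.16e-05) and without any 1 array. With no filter, 20 of 21 members were higher (mean 0.21; adjusted p = 1.11e-04 with an estimated correlation). Over all genes 2 members passed, Ly86 and Ctss, and 7 did adjusted over the list alone, which adds the complement genes C1qa (0.24), C1qb (0.25) and C1qc (0.37), the receptor gene Csf1r (0.19) and Fcrls (0.36). The other tested members were Tyrobp (0.19), Siglech (0.13), Trem2 (0.11), Tmem119 (0.09), Cd68 (0.09) and Cx3cr1 (0.08), each at adjusted p = 0.9996 over all genes. At 6 h the same list averaged 0.04 higher (adjusted p = 0.787), with 1 member past the threshold adjusted over the list alone, C1qa (0.19). At 1 day it averaged -0.00 (adjusted p = 0.795), with 1 adjusted over the list alone, the fractalkine receptor gene Cx3cr1, at -0.19 (adjusted p = 0.652 over all genes, lower in 3 of 3 arrays). Beside it at 4 days, astrocyte markers averaged -0.01 (adjusted p = 0.275), oligodendrocyte markers -0.03 and pan-neuronal markers -0.02, and endothelial and pericyte markers 0.07. The short non-coding and histone transcripts listed for RNA quality averaged 0.17 at 4 days. With no filter they averaged 0.21, with 10 of 11 higher (adjusted p = 5.43e-05, and adjusted p = 0.204 with an estimated correlation).

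**Figure D2:**
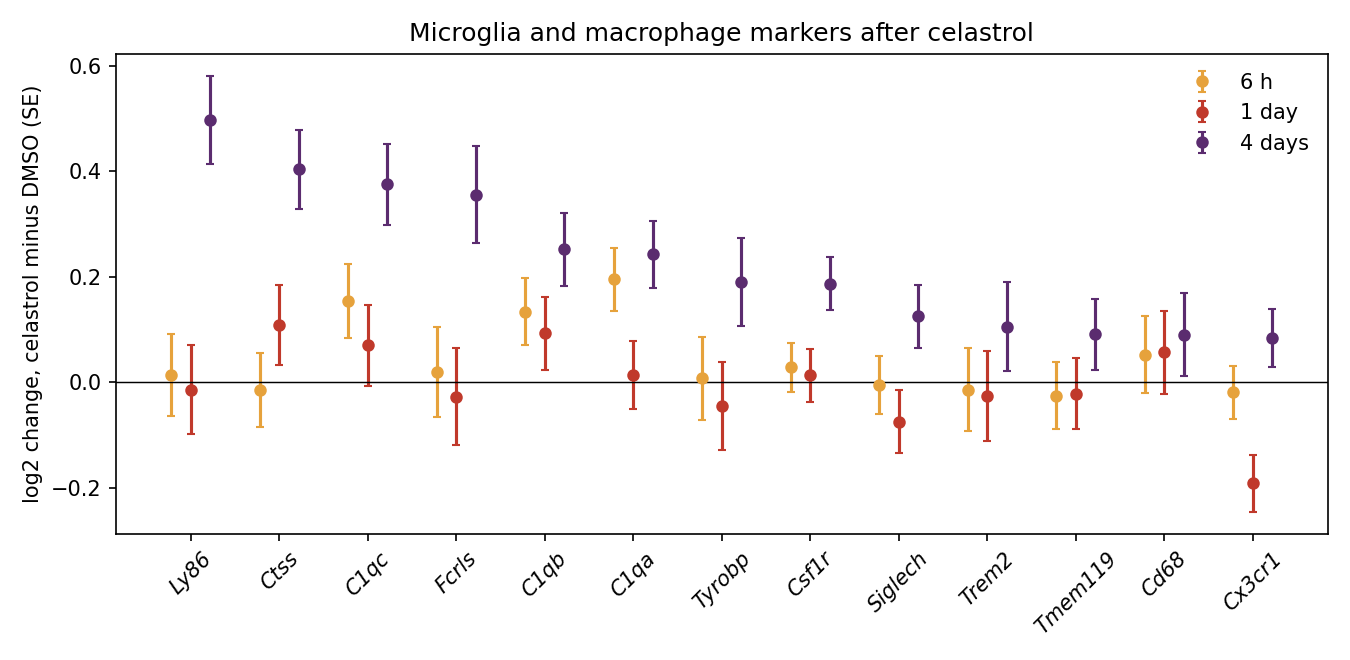
Log2 change, celastrol against DMSO (vertical axis), of the 13 tested microglia and macrophage markers (horizontal axis) at 6 h, 1 day and 4 days. Points are limma estimates and bars are ± SE, with 4, 3 and 3 celastrol arrays against 4 DMSO arrays. At 4 days all 13 lie above 0, and Ly86 is at 0.50.

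The acute-phase list rose at 4 days with all 10 tested members higher (mean log2 change 0.41, 95% interval 0.21 to 0.62; adjusted p = 9.44e-11, and 0.00326 with an estimated correlation), 1 over all genes and 5 adjusted over the list alone, Lcn2, Ptgs2, Nfkbia, Vcam1 and C4b. Lcn2 and Ptgs2 entered the tested set through celastrol arrays alone. With no filter, 23 of 37 members were higher and the mean was 0.16 (adjusted p = 6.99e-05), and the call was lost with an estimated correlation (adjusted p = 0.230). Without Lcn2 the mean was 0.24 (adjusted p = 4.11e-09, and 0.00484 with an estimated correlation). In all, 12 lists were called at 4 days with the preset correlation, 8 higher and 4 lower, and 2 with an estimated correlation and by fry. Of the 10 lost that way, glucocorticoid response genes had 22 of 24 members higher (mean 0.14; adjusted p = 7.28e-08, and adjusted p = 0.247 with an estimated correlation), 0 over all genes and 3 adjusted over the list alone, Sgk1, Nfkbia and Ddit4. The leptin and JAK-STAT3 list averaged 0.12 higher (adjusted p = 3.98e-04, and adjusted p = 0.206 with an estimated correlation), 0 over all genes and 2 adjusted over the list alone, Osmr and Fosl2. Endothelial and pericyte markers had 14 of 19 higher (mean 0.07; adjusted p = 0.00934, and adjusted p = 0.395 with an estimated correlation), with Tek and Vwf past the threshold adjusted over the list alone and 0 over all genes. Short non-coding and histone transcripts had 4 of 5 higher (mean 0.17, adjusted p = 0.0183, and adjusted p = 0.288 with an estimated correlation). They were listed as a possible sign of RNA quality, and no direct measure of it was used here. Immediate early genes averaged 0.06 (adjusted p = 0.0251, and adjusted p = 0.288 with an estimated correlation), and fasting genes 0.06 (adjusted p = 0.0419, and adjusted p = 0.428 with an estimated correlation).

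The 4 lists with lower values at 4 days were heat shock genes, 5 of 22 members higher (mean -0.03; adjusted p = 0.0104, and adjusted p = 0.428 with an estimated correlation), cholesterol biosynthesis, 4 of 21 (-0.04; adjusted p = 0.00269, and adjusted p = 0.288), oligodendrocyte markers, 5 of 19 (-0.03; adjusted p = 0.0183, and adjusted p = 0.288) and pan-neuronal markers, 6 of 22 (-0.02; adjusted p = 0.0183, and adjusted p = 0.288). Leaving out arrays ended 7 of the 12 calls. Without celastrol 4 days replicate 3 the heat shock (-0.02), fasting (0.04), immediate early (0.03), oligodendrocyte (-0.04) and neuronal (-0.03) calls were lost. Without celastrol 4 days replicate 2 the heat shock (-0.02), fasting (0.05), endothelial (0.05) and neuronal (-0.01) calls were lost, and without celastrol 4 days replicate 1 the oligodendrocyte (-0.01) and RNA quality (0.10) calls. Without DMSO 4 days replicate 4 the heat shock (-0.02), fasting (0.05), immediate early (0.06), oligodendrocyte (-0.02) and neuronal (-0.02) calls were lost. Without DMSO 4 days replicate 2 the fasting (0.04), immediate early (0.04) and endothelial (0.05) calls were lost, without replicate 3 the fasting (0.06), endothelial (0.06) and RNA quality (0.13) calls, and without replicate 1 the oligodendrocyte call (-0.02). Without DMSO 6 h replicate 2 the fasting call was lost (0.06), as it was with no filter (adjusted p = 0.0986). The replicate block ended the heat shock (-0.02, adjusted p = 0.114) and oligodendrocyte (adjusted p = 0.0817) calls, and quantile normalization again the neuronal call (adjusted p = 0.0775).

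**Figure D3:**
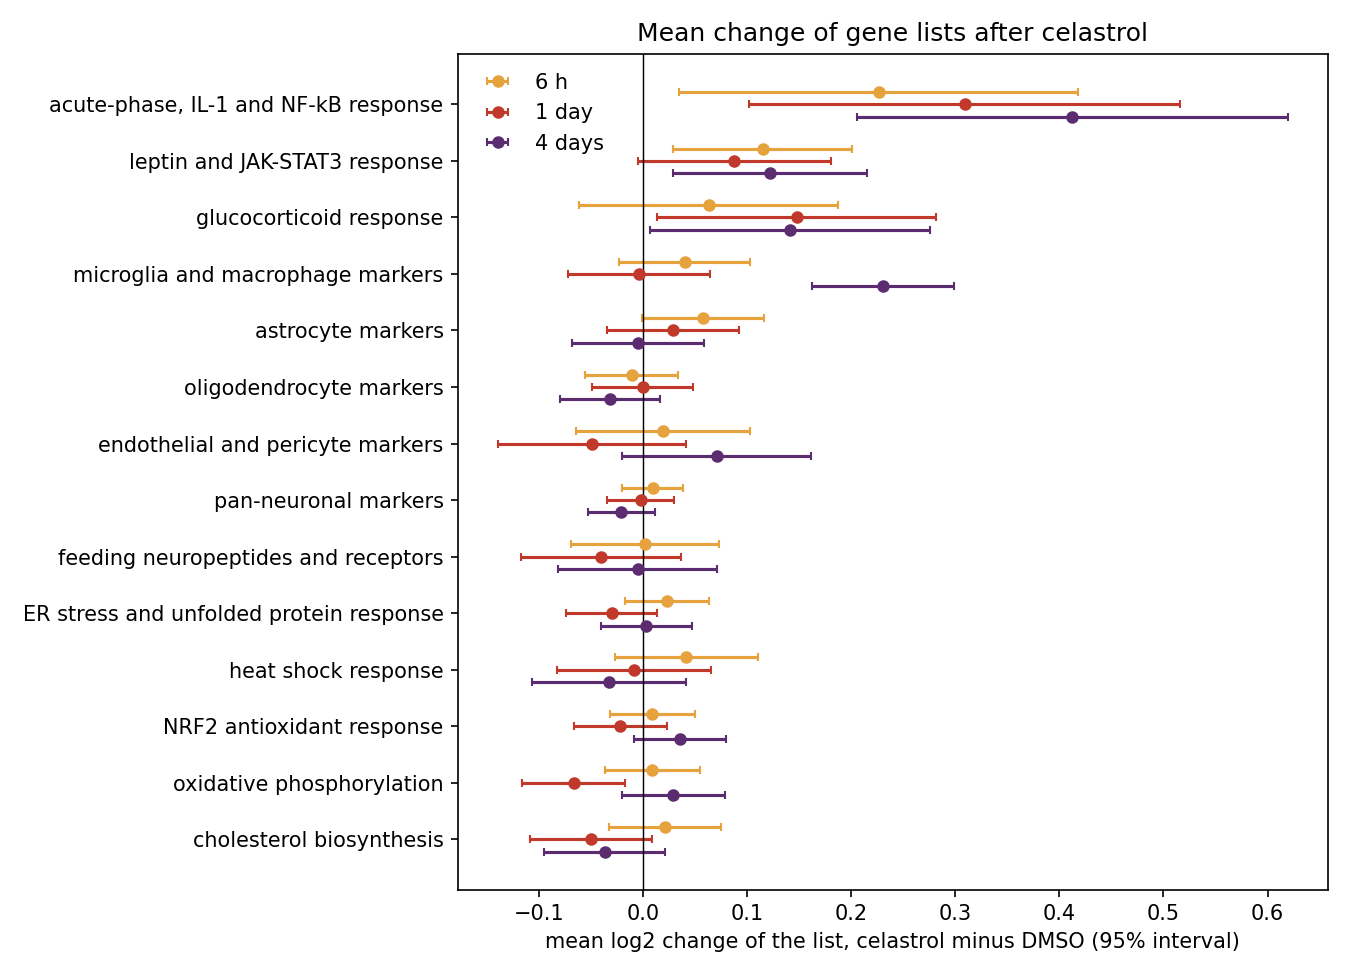
Mean log2 change, celastrol against DMSO (horizontal axis), of 14 gene lists (vertical axis) at 6 h, 1 day and 4 days; bars are 95% intervals over arrays, with 4, 3 and 3 celastrol arrays against 4 DMSO arrays. The microglia and macrophage list is at 0.04, -0.00 and 0.23.

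Genes of appetite control, named at every time because celastrol is known as an appetite-lowering compound, did not pass at any time. Pomc, the melanocortin precursor, differed by -0.11 (SE 0.13), -0.13 (SE 0.14) and 0.04 (SE 0.14) at 6 h, 1 day and 4 days, and its average was -0.07 (95% interval -0.23 to 0.09, adjusted p = 1, lower in 7 of 10 arrays). Npy, the orexigenic neuropeptide Y, differed by 0.04, -0.07 and 0.06, with an average of 0.01 (95% interval -0.17 to 0.19). Hspa5, the endoplasmic reticulum chaperone BiP, differed by 0.04, 0.02 and -0.00, with an average of 0.02 (95% interval -0.04 to 0.08). The leptin receptor gene Lepr and its feedback inhibitor Socs3 were too dim for the tested set. Without the filter Lepr differed by -0.02, -0.04 and 0.25, and Socs3 by 0.11, 0.08 and 0.03, none past the threshold. Il1r1 and Agrp were not analysed here.

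Of the 26 lists, 10 were called in none of the celastrol comparisons. Their mean log2 changes over the 3 times were -0.01 for 27 feeding neuropeptide and receptor genes (95% interval -0.06 to 0.03, adjusted p = 0.383) and -0.00 for 29 genes of the unfolded protein response (95% interval -0.03 to 0.02, adjusted p = 0.579). They were 0.01 for NRF2 targets (adjusted p = 0.659), 0.02 for interferon response (0.888), 0.01 for the circadian clock (0.708), 0.02 for ependymal cells and tanycytes (0.659) and -0.00 for neighbouring forebrain (0.659). They were -0.08 for the 2 tested choroid plexus genes (0.888), -0.01 for the 2 tested blood cell genes (95% interval -0.04 to 0.03, adjusted p = 0.659) and -0.03 for meninges (95% interval -0.33 to 0.27, adjusted p = 0.470). The direction of the test differed from the sign of the mean or of the median for 8 of 26 lists at 6 h, 9 at 1 day, 5 at 4 days and 4 on the average. None of these was a called list.

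Whether the response to celastrol differed between times was tested directly. Microglia and macrophage markers rose more at 4 days than at 6 h, by 0.19 on the log2 scale (95% interval 0.10 to 0.28, 13 of 13 members; adjusted p = 8.94e-11, and 0.0048 with an estimated correlation), and more than at 1 day, by 0.23 (95% interval 0.14 to 0.33, 13 of 13; adjusted p = 2.85e-08, and 0.0166 with an estimated correlation). Over all genes 0 members passed, and adjusted over the list alone 2 did against 6 h and 8 against 1 day. No gene passed for any of the 3 differences by limma (lowest adjusted p 0.581, 0.280 and 0.138), while 817, 334 and 593 had an unadjusted p under 0.05.

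For 4 days minus 6 h, the genes of the rule with higher values were Sgk1, a glucocorticoid-induced kinase gene (1.22, SE 0.28, adjusted p = 0.474), Ddit4 (0.63, SE 0.12, adjusted p = 0.280), Nfkbia (0.55), Vwf (0.52) and Ly86 (0.48), and those with lower values Idh1 (-0.51), Ndnf (-0.43), Id2 (-0.29), Mtmr6 (-0.26) and Hepacam (-0.22). Ddit4 alone passed when DMSO 4 days replicate 3 was left out, for a count of 1. For 1 day minus 6 h they were Nfkbia (0.52), Ddit4 (0.43), Lgals3 (0.36), Adamts9 (0.28) and Leng8 (0.26), and Sde2 (-0.36), Zfp622 (-0.35), Psmd10 (-0.34), Mocs2 (-0.30) and Exoc3 (-0.22), all at adjusted p = 0.581. For 4 days minus 1 day they were Ly86 (0.51, adjusted p = 0.465), Tek (0.41, SE 0.07, adjusted p = 0.138), Utp15 (0.35), Spata7 (0.35) and Rpf2 (0.30), and Zranb3 (-0.30), Id2 (-0.29), Idua (-0.24), Syt6 (-0.22) and Rap1gap2 (-0.21). Tek passed with the leading residual component as a covariate, for a count of 1. The lists called with the preset correlation numbered 4, 9 and 5 for 1 day minus 6 h, 4 days minus 6 h and 4 days minus 1 day, and 0, 1 and 1 with an estimated correlation and by fry, the microglial list in each case. For 1 day minus 6 h the glucocorticoid list had a median of -0.00 against a mean and test above 0 (0.08), and the signs differed for 11, 4 and 7 of the 26 lists.

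Across genes, the log2 changes of the 3 times correlated weakly. Pearson r was 0.03 between 6 h and 1 day, 0.04 between 6 h and 4 days and 0.05 between 1 day and 4 days, and Spearman rho was -0.11, 0.05 and -0.10, over 9880 genes, which are not independent replicates. The sign was shared by 43.0%, 53.0% and 45.4% of genes. Of genes with an unadjusted p under 0.05 at both times there were 44, 33 and 38, where independent lists give 33.6, 18.5 and 24.1. Of these, 20, 27 and 17 shared the sign. The comparisons have separate controls. Leaving out 1 array moved r between -0.08 and 0.15, -0.03 and 0.13, and -0.02 and 0.10.

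The DMSO arrays alone showed how the background differed between times. Between 6 h and 4 days 25 genes changed, 12 higher and 13 lower at 4 days (limma; 1507 at an unadjusted p under 0.05; n = 4 each). Naa20, a subunit of an amino-terminal acetyltransferase, fell by 0.43 (SE 0.06, adjusted p = 0.00803), Ociad2 fell by 0.43 (adjusted p = 0.0335) and Scrg1 fell by 0.31 (adjusted p = 0.0473). The glycine receptor gene Glra3 rose by 0.31 (adjusted p = 0.0189), the neurotensin receptor gene Ntsr1 by 0.28 (adjusted p = 0.0335) and Dcaf17 by 0.27 (adjusted p = 0.0335). In each of these, all 4 arrays of 1 time lay above all 4 of the other, which relabelling gives with an exact probability of 0.0286. The count was 0 with only the groups compared, 1 with no filter on level (Naa20) and 1 with the replicate block. It was 45 with limma-trend, 53 with all probe sets, 105 with array weights, 115 with the residual component and 52 without the 2 least typical arrays. The adjusted p with no filter was 0.0781 for Glra3, 0.0938 for Ntsr1, 0.0937 for Dcaf17, 0.105 for Ociad2 and 0.134 for Scrg1. With arrays left out, the count was 147 without DMSO 6 h replicate 3. It was 16 without celastrol 1 day replicate 3 or celastrol 4 days replicate 1, 15 without DMSO 1 day replicate 2 or 3, 14 without DMSO 1 day replicate 4 or celastrol 6 h replicate 3 or 4, and 12 without celastrol 4 days replicate 2. It was 7 without DMSO 6 h replicate 4 or DMSO 4 days replicate 1, 6 without DMSO 4 days replicate 2, 4 without DMSO 6 h replicate 1, 2 without DMSO 6 h replicate 2, 1 without DMSO 4 days replicate 4 and 0 without DMSO 4 days replicate 3.

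Between 1 day and 4 days of DMSO 15 genes changed, 5 higher and 10 lower at 4 days (1448 at an unadjusted p under 0.05). Mgat2, a Golgi glycosylation enzyme, fell by 0.30 (SE 0.04, adjusted p = 0.00467), Tubb2b, a tubulin of developing neurons, fell by 0.32 (adjusted p = 0.0447) and Dnajc12 fell by 0.28 (adjusted p = 0.0275). Leng8 rose by 0.29 (adjusted p = 0.0230), Pex5l by 0.26 (adjusted p = 0.0339) and Trerf1 by 0.25 (adjusted p = 0.0331), again with no overlap between the arrays. The count was 0 with only the groups compared, 1 with no filter on level (Mgat2), 1 with the replicate block and 5 without the 2 least typical arrays. It was 24 with the stricter filter, 25 with robust variances, 29 with the mean of probe sets, 37 with quantile normalization again, 47 with limma-trend, 69 with all probe sets, 106 with the residual component and 168 with array weights. With arrays left out, it was 9 without celastrol 4 days replicate 3, 5 without DMSO 1 day replicate 1 or DMSO 4 days replicate 1, 4 without DMSO 4 days replicate 2, 2 without DMSO 4 days replicate 3, and 1 without DMSO 1 day replicate 3 or DMSO 4 days replicate 4.

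Between 6 h and 1 day of DMSO 0 genes passed by limma (lowest adjusted p = 0.0593) and 1389 had an unadjusted p under 0.05, 1148 higher and 241 lower at 1 day. The genes named by the rule were Park7 (0.34), Laptm5 (0.30), Exoc3 (0.19), Nuak1 (-0.49) and Fabp7 (-0.43), all at adjusted p = 0.0593, and Rpl10a (-0.16, adjusted p = 0.104), with no overlap between the arrays. The count was 10 with the stricter filter, 10 with robust variances, 12 with limma-trend, 13 with array weights, 30 with the residual component and 2 without the 2 least typical arrays. Leaving out DMSO 6 h replicate 3 gave 46 genes, celastrol 6 h replicate 1 15, celastrol 4 days replicate 2 6, and DMSO 6 h replicate 4 or DMSO 1 day replicate 4 1 each.

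Lists moved in DMSO as well, all lower at the later time and none with an estimated correlation or by fry. Glucocorticoid response genes averaged -0.10 at 4 days against 6 h (adjusted p = 1.94e-07, and adjusted p = 0.464 with an estimated correlation), with 0 over all genes and 6 adjusted over the list alone, among them Sgk1, Mt2 and Ddit4. At 4 days against 1 day they also averaged -0.10 (adjusted p = 0.00121, and adjusted p = 0.518 with an estimated correlation), the acute-phase list -0.12 (adjusted p = 0.0317, and adjusted p = 0.518) and oxidative phosphorylation genes -0.07 (adjusted p = 1.37e-05, and adjusted p = 0.518). The other calls at 4 days against 6 h were pituitary markers (-0.55, adjusted p = 0.0269), RNA quality transcripts (-0.34, adjusted p = 6.43e-04), heat shock genes (-0.04, adjusted p = 0.00715), hypothalamic regional markers (-0.05, adjusted p = 7.89e-04), ependymal markers (-0.05, adjusted p = 0.0431), feeding neuropeptides (-0.02, adjusted p = 0.0431) and oxidative phosphorylation genes (-0.01, adjusted p = 0.0269), with adjusted p between 0.395 and 0.478 with an estimated correlation. Of their members Uqcrh, of the respiratory chain, passed over all genes. At 1 day against 6 h it was the RNA quality transcripts (-0.30, adjusted p = 0.0171, and adjusted p = 0.906 with an estimated correlation).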

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

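The tests weighed for the patterns here were all chosen before their results were seen. The 6 genes called on the average over the 3 times were higher after celastrol. More blood vessel cells are argued against: the upper 95% bound of the mean change of the endothelial and pericyte list was 0.0646, below the smallest called change, 0.14 for Sbno2. A single array is argued against too, since at least 4 of the 6 called genes were kept when any 1 of the 22 arrays was left out (4 without celastrol 1 day replicate 1 or celastrol 4 days replicate 1). More blood cannot be told apart from a response of the tissue, although the upper bound of the blood cell list was 0.0254. Of its 24 genes only 16 had a probe set with exactly 1 symbol, and of these only 2, Fech and Bpgm, were bright enough to test. The bound set beforehand was therefore no fair test. With no filter on level, 16 blood genes had a mean of 0.02 on the average, 10 of them higher, and of 0.06 at 1 day, 13 of them higher. The genes so added were dim, with no measured background, so these values do not settle the question. A response of hypothalamic cells to celastrol therefore stays a hypothesis, which may hold beside these explanations.

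Microglial genes were higher after 4 days of celastrol, with a mean of 0.23. A lower share of neurons is argued against, since it would raise astrocyte and oligodendrocyte markers alike: the microglial list exceeded them by 0.24 and 0.26, and the lower of both lower 95% bounds was 0.156. A single array is argued against, because at least 91.8% of the mean change was kept without any 1 of the 7 arrays of 4 days (lowest without DMSO 4 days replicate 2). More blood in the celastrol samples, with an upper bound of 0.0893 on the 2 tested blood genes, cannot be told apart, for the same shortage of tested genes. With no filter, 16 blood genes averaged 0.03 at 4 days, 10 of them higher, against 0.21 for the microglial list, but the genes so added were dim. The rise was uneven over the microglial list, which also covers macrophages, from 0.08 for Cx3cr1 and 0.09 for Tmem119 to 0.50 for Ly86. More microglia or macrophages, or stronger expression per such cell, could each raise the list. They were not tested against each other, nor against RNA quality, whose list averaged 0.17 at 4 days.

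The DMSO arrays differed between times. Time of day as the whole source is argued against by the 18 tested clock genes, whose median change reached at most the 37.4th percentile of 10000 random lists matched on level. Between DMSO times there were 40 calls. They include 4 genes called in both comparisons and counted in each, and both comparisons share the arrays of 4 days. Handling of the arrays of each time as a batch has the values it needs: 39 of the 40 calls (97.5%) moved the same way between the celastrol times, 25 of 25 and 14 of 15. The duration of treatment predicts the same, so a batch and the time likely cannot be separated by these arrays. Comparisons of celastrol with DMSO were made within a time and do not cross batches of that kind. Whether DMSO and celastrol arrays of a time differed in handling was not tested.

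For the 5 genes at 4 days, 1 of 35 splits of the 7 arrays, the real one, gave as many and the highest other gave 1. Without some single arrays, with the replicate block and with all probe sets their count fell to 0, so chance is left open. Chance is argued against as the source of the count of 6 on the average (1 of 100 splits, highest other 1). At least 4 of these 6 genes were kept without any 1 array. For the 25 and 15 genes between DMSO times the real split was again the highest (1 of 35 each, highest others 1 and 0). Both counts fell to 0 with only the groups compared, so chance is left open for them too. For lists at 4 days the real count of 12 was the highest (1 of 35; highest other 10), but it fell to 8 without 1 array and only 2 of the 12 held with an estimated correlation, so chance is left open. A share of 1 in 35 is the smallest that 35 splits can give, and no correction was made over the split tests. It cannot be excluded for the 5 lists at 6 h (8 of 35; highest other 10), the 5 lists at 1 day (10 of 35; highest other 10) and the 7 lists of the average (17 of 100; highest other 12). With a real count of 0 all splits gave as many: 35 of 35 at 6 h (highest other 12), at 1 day (2) and for DMSO 1 day minus 6 h (1), and 100 of 100 for the differences 1 day minus 6 h (highest other 85), 4 days minus 6 h (15) and 4 days minus 1 day (1). Splits that called 12, 85 and 15 genes where the real one called 0 may point to a structure of the samples, and what made them call genes was not tested.

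Differences between groups, here of the celastrol effect between times, were found by a direct test with a preset correlation for 18 pairs of list and times. For 1 day minus 6 h, the glucocorticoid list differed by 0.0846, oxidative phosphorylation by -0.0756, pituitary markers by 0.41 and hypothalamic regional markers by 0.0549. For 4 days minus 6 h, the differences were -0.0745 for heat shock, 0.19 for the acute-phase list, 0.0782 for glucocorticoid response, -0.0584 for cholesterol biosynthesis, -0.0627 for astrocyte, 0.19 for microglia, 0.0514 for endothelial, 0.73 for pituitary and 0.19 for RNA quality transcripts. For 4 days minus 1 day, they were 0.10 for oxidative phosphorylation, -0.0341 for astrocyte, 0.23 for microglia, -0.0315 for oligodendrocyte and 0.12 for endothelial markers. The pituitary, RNA quality and glucocorticoid lists were themselves called lower in DMSO at 4 days than at 6 h. Oxidative phosphorylation was called lower in DMSO at 4 days than at 1 day. These differences can therefore come in part from the DMSO arrays. The pituitary change at 6 h, which enters both pituitary differences, was -0.51 with all arrays and -0.23 without DMSO 6 h replicate 4. With an estimated correlation 2 of the 18 differences held, both microglial.

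A signal in genes outside the main measurement was found with no filter on level, where sizes of change are uncertain because no background level was measured. Ch25h, which makes the oxysterol 25-hydroxycholesterol in inflammation, had a mean log2 level of 6.88, below the lower quartile of each array, and was higher by 0.84 at 1 day (SE 0.12, adjusted p = 0.0114), 0.95 at 4 days (SE 0.12, adjusted p = 0.00163) and 0.68 on the average (SE 0.07, adjusted p = 3.35e-05). At 4 days Itgam, the CD11b integrin of myeloid cells, was higher by 0.32 (adjusted p = 0.0463) and Wfdc17 by 0.65 (adjusted p = 0.0170). On the average Slfn5 was higher by 0.26 (adjusted p = 0.0219) and Srarp by 0.28 (adjusted p = 0.0101).

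A sample far from the others of its group was found in 27 of 408 tests (102 genes and lists in the 4 groups of 4 arrays), where chance marks about 1 in 20 groups, or 20.4. Values are log2 levels. In DMSO 6 h, replicate 1 was lowest for Lcn2 (6.67), Vma21 (9.99) and the microglial list (9.40). Replicate 2 of that group was lowest for Fosl2 (8.47) and C1qc (9.76) and highest for Psmd10 (10.01) and heat shock (10.97), and replicate 3 highest for meningeal markers (9.56). In celastrol 6 h, replicate 3 was highest for Vps26c (10.15) and endothelial markers (9.69), replicate 4 lowest for Ctss (9.61) and replicate 2 lowest for oligodendrocyte markers (10.77). In DMSO 1 day, replicate 1 was highest for Vps26c (10.11), Psmd10 (10.24), Park7 (12.24) and ependymal markers (10.12) and lowest for Ociad2 (10.23), and replicate 2 lowest for Lcn2 (6.61) and fasting genes (9.66). Replicate 3 of that group was highest for Gh (10.98), choroid plexus (8.91) and meningeal markers (10.09) and lowest for Pank3 (9.42). In DMSO 4 days, replicate 2 was lowest for Zfp622 (9.27) and highest for Scrg1 (10.48), replicate 1 lowest for Dcaf17 (8.96) and replicate 4 highest for choroid plexus markers (8.65).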

How the results depend on the processing

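The setting without the 2 least typical arrays, that of lists with no filter and an estimated correlation together, and the acute-phase list without Lcn2 were chosen after the results were seen. Under alternatives other than leaving out 1 array, 1408 of 1530 values of single genes kept their direction and their side of the threshold, 72 lost and 47 gained a call, and 3 reversed. A gene called in neither setting counts as kept, and many of these genes were not called to begin with. The share kept therefore says little about how stable the calls are. For single lists 123 of 207 were kept and 84 lost. Counts and correlations moved in 50 of 159 cases. The 8824 genes below the filter on level were outside the counts, and no background level was measured. The cause was not tested except where a setting changes how many genes or arrays enter.

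With no filter on level, 1 gene was called at 1 day, 3 at 4 days (0 shared with the 5 reported), 1 for DMSO 4 days minus 6 h and 1 for DMSO 4 days minus 1 day. The stricter filter, which left Osmr, Ptgs2, Ier3 and Sbno2 untested, gave 1 on the average, Acer2 (0.38, adjusted p = 0.0266), 10 for DMSO 1 day minus 6 h and 24 for DMSO 4 days minus 1 day. The mean of probe sets gave 29 for DMSO 4 days minus 1 day. Quantile normalization again gave 3 at 4 days, 37 for DMSO 4 days minus 1 day, and reversed Hspa5 at 4 days (0.00932). Limma-trend gave 8 at 4 days and, for DMSO, 12 (1 day minus 6 h), 45 (4 days minus 6 h) and 47 (4 days minus 1 day). Robust eBayes gave 1 at 4 days, 10 for DMSO 1 day minus 6 h and 25 for DMSO 4 days minus 1 day. Array weights, from 0.289 for DMSO 1 day replicate 1 to 3.29 for celastrol 1 day replicate 3 and stopped by limma with a warning before full convergence, gave 5 at 1 day, 16 at 4 days and 13, 105 and 168 for DMSO. The residual component gave 5 at 1 day, 13 at 4 days, 1 for the difference 4 days minus 1 day and 30, 115 and 106 for DMSO. Only the groups compared gave 0 for DMSO 4 days minus 6 h and 0 for 4 days minus 1 day, and 7 genes at 4 days, 1 of them shared; it was not run for the average, which needs all groups. All probe sets gave 0 at 4 days, 53 for DMSO 4 days minus 6 h and 69 for 4 days minus 1 day. Without the 2 least typical arrays there were 3 genes at 4 days, 2, 52 and 5 for DMSO and 3 lists at 1 day, and Npy at 1 day reversed (0.0576). Lists called with an estimated correlation, and by fry alike, were 0 at 6 h, 0 at 1 day, 2 at 4 days and 4 on the average; with no filter and an estimated correlation they were 0, 0, 1 (microglia) and 4.

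The replicate numbers could mark pairs, so the replicate number was fitted as a block (replicate block) and the pairing was checked. Deviations of equal numbers from their group means correlated between -0.24 and 0.41 across genes, above 0 in 4 of 10 pairs and highest for replicates 3 (0.41) and 2 (0.18) at 6 h, so whether the numbers mark pairs stays open. The replicate block gave 6 genes on the average (5 shared), 0 at 6 h, 0 at 1 day, 0 at 4 days, 0 for the 3 differences between times, 0 for DMSO 1 day minus 6 h and 1 for each other DMSO comparison, and it reversed Npy on the average (-0.00904); the cause was not tested.

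Leaving out each array in turn gave 0 to 4 genes at 1 day, 0 to 9 at 4 days, 4 to 9 on the average, 0 to 1 for the difference 4 days minus 6 h, and 0 to 46, 0 to 147 and 1 to 22 for DMSO. Lists called ranged from 0 to 9 at 6 h, 3 to 5 at 1 day, 8 to 12 at 4 days and 6 to 12 on the average. Values that changed sign ranged, for Hspa5, from -0.0183 to 0.0568 at 1 day and -0.0180 to 0.0164 at 4 days. They ranged for Npy from -0.0611 to 0.13 at 6 h, -0.18 to 0.0829 at 1 day, -0.0531 to 0.16 at 4 days and -0.0282 to 0.0608 on the average, and for Pomc from -0.20 to 0.00869 at 6 h and -0.10 to 0.17 at 4 days.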

Other observations

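Of the tests given here, the relation of Lcn2 with the called genes was chosen only after its result was seen. No difference between times passed for any gene, so the courses of the called genes are given as values alone. Acer2 was higher by 0.24, 0.34 and 0.56 at 6 h, 1 day and 4 days, and Ier3 by 0.12, 0.29 and 0.32. The Ier3 means were 8.62, 8.69 and 8.61 after celastrol and 8.50, 8.41 and 8.29 after DMSO. The Lcn2 means were 8.55, 8.71 and 8.60 after celastrol and 7.25, 6.91 and 6.64 after DMSO. For both genes the larger difference at 4 days than at 6 h thus came from lower DMSO means. Sbno2 was higher by 0.09, 0.22 and 0.10, and Adamts9 by 0.01, 0.29 and 0.17. Of genes that passed at no time, Sgk1 differed by -0.38, 0.54 and 0.84, Ddit4 by -0.18, 0.26 and 0.45, and Nfkbia by -0.15, 0.36 and 0.40. The endothelial gene Vwf differed by -0.06, 0.09 and 0.46.

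Celastrol arrays differed widely in Lcn2, and a hypothesis is that each animal had 1 strength of response, shared by the called genes. Over the 10 celastrol arrays, deviations of Lcn2 from its group means correlated with those of the mean of the 6 called genes at Pearson r = 0.690 (permutation p = 0.0739) and Spearman rho = 0.636 (permutation p = 0.0994), and at r = 0.847 without the 2 farthest arrays. The adjusted p over the 4 relations computed was 0.295, so the values could go with the hypothesis but do not establish it. With the glucocorticoid response list r was 0.534 (permutation p = 0.265) and rho 0.430 (permutation p = 0.335), and r was 0.431 without the 2 farthest arrays (adjusted p = 0.361). Over the 12 DMSO arrays r was 0.31 (permutation p = 0.299) with the called genes and 0.30 (permutation p = 0.361) with the glucocorticoid list. Without the 2 farthest DMSO arrays r was 0.386 with the called genes and 0.602 with the glucocorticoid list. The latter is above the 0.431 of the celastrol arrays, so that relation was not particular to celastrol.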
